A study of Monodelphis domestica with 16 samples.

How the data were processed

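RNA-seq libraries from brain and extra-embryonic membranes (EEM) of 8 opossum fetuses (16 libraries) were grouped by tissue, cross and sex as the labels give them. Per the labels' protocols, tissue was collected 13 days after copulation into a preservative or buffer, the head or brain was dissected, and RNA was extracted, treated with DNase and made into libraries with a TruSeq RNA kit. The submitters' processing notes name CASAVA 1.7, TopHat 1.4.1, Cufflinks 1.3.0 and SAMtools, with no role or order. Their settings, the genome build, the gene annotation and the normalization are not given in the sources used here.

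The deposited values are FPKM per gene, in 1 table for brain (15180 lines) and 1 for EEM (14059 lines), with 8 libraries each. The values show a step that no source describes: within a table, 88.9% (brain) and 90.1% (EEM) of ranks hold the same value in all 8 libraries within a relative tolerance of 1e-06, as quantile normalization would leave them. This forces the libraries of a table to nearly the same distribution. Differences in total RNA output, and any overall rise or fall of expression, are removed by such a step, and a large change in part of the genes can shift the others. The 2 tables do not share that distribution. Tests of differences in expression were therefore made within a table only, and the tests of brain against EEM that had been planned were not run. The check for membrane tissue in F1 brain libraries does set values of both tables against each other. No value is 0 in either table. Depth is unknown, so no counting interval can be given, and genes with low FPKM or short spans are less precise than others by an amount that cannot be stated.

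Identifiers listed more than once were left out (5 identifiers on 10 lines in brain, 2 on 4 lines in EEM), which left 15170 and 14055 genes. The tables hold Ensembl gene identifiers and positions without symbols, and 0 of them matched the reference gene table (assembly mMonDom1). The gene lists fixed before the data were examined consist of symbols and could not be used. All values per library were matched to a sample by name.

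Each comparison was fitted with limma 3.58.1 (R 4.3.3) with a mean-variance trend, on log2(FPKM + 1), over genes with a mean of at least 1 FPKM in the table (13081 in brain, 11873 in EEM), with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount of 1 understates fold changes of low genes, and printed folds from limma are on that scale. The sex, reciprocal cross and line comparisons came from 1 fit of all 8 libraries of a tissue with a term for each of the 4 crosses and a term for sex, so that sex is compared within the parental litters. F1 and parental fetuses were compared with sex as a covariate. All F1 fetuses were female, so the sex term took up the parental males. The fitted F1 changes, folds and p-values therefore compare F1 with the parental females alone, 1 from each parental litter. The parental males enter only the estimate of the spread. These designs were fixed before the data were examined, and had assumed tests between tissues as well. Chromosomes were tested as gene sets with camera at a preset correlation of 0.01 and again with an estimated correlation. The X-to-autosome ratio and the median mitochondrial FPKM were compared by two-sided exact permutation tests. X-linked counts were set against 10000 sets of autosomal genes matched on expression.

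Named genes followed a rule fixed before the data were examined: up to 6 genes per direction by absolute log2 change among those past the threshold for the cross, line and F1 comparisons, or the 3 with the smallest p where none passed; X-linked genes past the threshold by sex, or the 5 with the smallest p; and the 5 X-linked genes with the highest mean. The rule asked for a symbol, which no gene had, so it was applied to all genes. X-linked genes at least 0.4 log2 higher in females of both litters, chromosome 6 neighbours and short genes were chosen after their values had been seen. Identifiers are printed for at most 2 genes per direction and comparison.

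The fits were tested on simulated data with 200 changed genes per comparison. Of the genes changed by 2 log2 units, 53% (sex), 29% (reciprocal crosses), 40% (lines) and 81% (F1 against parental) were recovered in brain, and 100% in each EEM comparison. Of those changed by 1 log2 unit, 0%, 0%, 0% and 43% were recovered in brain in the same order, and 92%, 91%, 92% and 81% in EEM. False calls numbered 3, 4, 0 and 3 in brain and 8, 12, 9 and 12 in EEM.

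Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter and a minimum of 5 FPKM, median ratio scaling, limma without a trend, fits of the parental or F1 libraries alone, females alone, litter as a random block (statmod 1.5.0), and leaving out each library. Alternatives added later were a term for the 2 F1 brain libraries numbered 4, leaving out those 2 or the other 2, leaving out genes under 300 bp, and other limits for the X-linked counts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.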

Results

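RNA was sequenced from the brain and the extra-embryonic membranes (EEM, the fetal membranes that contribute to the placenta) of 8 opossum fetuses (Monodelphis domestica) at embryonic day 13, which gave 16 libraries. The fetuses came from 4 crosses of 2 parental lines, LL1 and LL2, with 2 littermates from each cross. The 4 F1 fetuses were all female, 2 with an LL2 mother and an LL1 father (LL2xLL1, mother named first) and 2 with an LL1 mother and an LL2 father (LL1xLL2). The LL1xLL1 and LL2xLL2 litters each gave 1 female and 1 male. Replicates of a cross are littermates, so litter and cross cannot be told apart, and p-values measure the spread between these embryos. The study concerned the X chromosome, of which females carry a pair and males a single copy, and its inactivation. In marsupials the copy inherited from the father is silenced in females. Allele-specific ratios are not used here. Values were FPKM (sequenced fragments relative to transcript length and to all mapped fragments), with 1 table for each tissue. The sequencing depth of each library is unknown because no counts were used, and the genome build of the coordinates is not given in the sources used here. The tables identify genes by identifier and position without symbols, and 0 identifiers matched the reference table, so genes are described by position.

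The brain table listed 15170 genes after duplicated identifiers were left out, 364 of them on the X chromosome, and the EEM table listed 14055, of which 315 were X-linked. Of the X-linked genes in the brain table, 54 (14.8%) were listed for brain and not for EEM, against 10.8% of all genes and 9.79% (chromosome 3) to 15.4% (chromosome 7) of those on single autosomes. Of those in the EEM table, 5 (1.59%) were listed for EEM and not for brain, against 3.75% of all genes and 2.89% (chromosome 6) to 4.46% (chromosome 4) on single autosomes. The X-linked gene with the highest mean level in both tissues lay at 3165611 to 3191300, with 5320 ± 1112 FPKM in brain and 4356 ± 859 FPKM in EEM (SD, n = 8). In brain it was followed by the genes at X 78791353 to 78792534 (5000 ± 1745 FPKM) and X 56152589 to 56153180 (4617 ± 1441 FPKM), and in EEM by the same genes in the other order, with 1935 ± 75.6 FPKM and 2676 ± 333 FPKM. The gene at X 72644965 to 72647167 was at 2133 ± 311 FPKM in brain and 1148 ± 102 FPKM in EEM. The gene at X 66981763 to 67025473 was among the 5 highest in EEM and not in brain, at 1889 ± 858 FPKM. The 2 tables appear to have been normalized separately, so levels in the 2 tissues are set side by side without a test.

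The level of the X chromosome as a whole was measured as the ratio of the median X-linked FPKM to the median autosomal FPKM, over genes with a mean of at least 1 FPKM (310 X-linked genes in brain, 242 in EEM). It was 0.953 ± 0.10 in brain and 1.03 ± 0.0686 in EEM (SD, n = 8 each). Single autosomes, measured in the same way, had mean ratios from 0.882 (chromosome 7, brain) to 1.12 (chromosome 2, EEM). In brain, the ratio was 1.04 ± 0.0326 in the F1 fetuses and 0.862 ± 0.0188 in the parental fetuses (SD, n = 4 each), with no overlap between them. A two-sided exact permutation test gave p = 0.0286, the smallest value that 70 splits allow. After adjustment over 8 tests it was 0.0762, so the difference did not pass the correction. These splits exchange littermates, which are not independent, and only 3 splits keep litters whole, too few for a p under 0.05. In EEM the F1 and parental ratios were 1.03 ± 0.101 and 1.03 ± 0.0257 (SD, n = 4 each; exact permutation p = 0.943). Males were at 0.858 ± 0.0293 in brain and 1.04 ± 0.00819 in EEM (SD, n = 2). Over all 8 libraries the exact permutation p for male against female was 0.214 in brain and 0.857 in EEM, a comparison that mixes sex with cross type because both males are parental and 4 of the 6 females are F1. Within the 4 parental libraries the exact permutation p was 1 in both tissues, where 6 splits allow no value under 0.333. The level of the ratio depended on which genes entered it: over genes with at least 1 FPKM in both tissues the brain ratio was 1.19, and over all listed EEM genes the EEM ratio was 0.803.

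**Figure D1:**
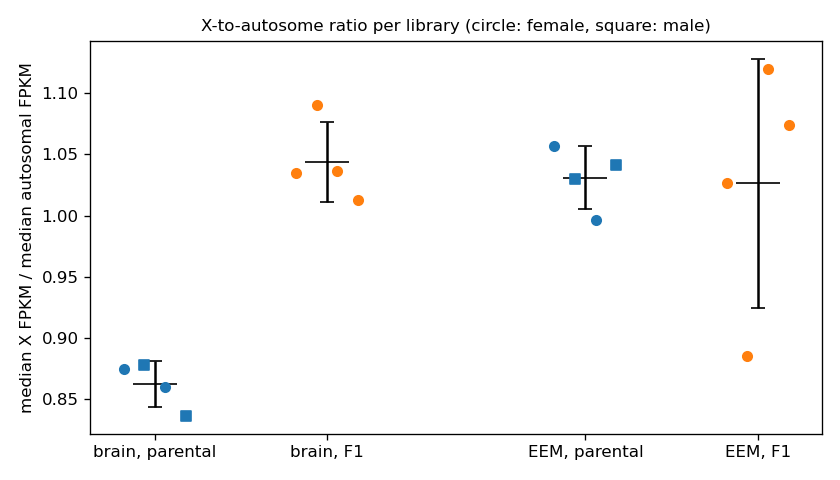
Ratio of the median X-linked FPKM to the median autosomal FPKM (vertical axis, no unit) in each of the 16 libraries, by tissue and by parental (blue) or F1 (orange) fetuses. Circles are females and squares are males, the horizontal bars are means and the whiskers are SDs (n = 4); the 4 F1 brain libraries lie between 1.01 and 1.09, above the 4 parental brain libraries at 0.837 to 0.878.

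Male and female littermates were compared to ask whether X-linked genes differ with the number of X chromosomes. The estimated male-to-female difference lay within 0.5 on the log2 scale for 302 of 310 X-linked genes (97.4%) in brain and 226 of 242 (93.4%) in EEM. The 95% interval of the difference lay above -1 for 176 of the brain genes (56.8%) and 233 of the EEM genes (96.3%), and for the others a 2-fold lower level in males is not excluded. The gene ENSMODG00000005735 at X 40254006 to 40263016 stood furthest from the rest in both tissues. In EEM it was at 296 ± 29.5 FPKM in females and 65.7 ± 5.75 FPKM in males of the parental litters (SD, n = 2 each), 4.45-fold higher in females, and it was the single gene of 11873 to pass the limma test (log2 male minus female -2.16, SE 0.12, adjusted p = 0.00417). In brain it was at 917 ± 7.64 FPKM in females and 192 ± 29.7 FPKM in males (SD, n = 2 each), 4.80-fold higher in females by the fit, with a log2 difference of -2.11 in the LL1xLL1 litter and -2.41 in the LL2xLL2 litter. The brain fit took its spread from all 8 libraries, of which the F1 libraries differed widely among themselves, and gave log2 -2.26, SE 0.39 and an adjusted p of 1 in limma. With the 4 parental libraries alone, limma gave an adjusted p of 5.32e-05 for this gene. Over all alternative fits its adjusted p ranged from that value to 1. After its cross and sex terms the parental fit has little left to estimate the spread, so its p-values and counts are less certain.

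Among the other X-linked genes that were higher in females, ENSMODG00000015320 at X 32853494 to 32887286 was at 9.47 FPKM in females and 3.31 FPKM in males in brain (2.43-fold) and at 3.60 against 1.75 FPKM in EEM (1.67-fold). The gene with the highest X-linked level, at X 3165611 to 3191300, was at 5721 ± 665 FPKM in female and 3653 ± 221 FPKM in male brain (SD, n = 2 each; 1.56-fold), and its ratio in EEM was 1.44-fold. A short gene inside it, at X 3166941 to 3167076, was 2.70-fold higher in females in brain and 2.79-fold in EEM. The 2 genes overlap and may share reads, so their values are uncertain. Neither they nor ENSMODG00000015320 passed the limma test over all 8 libraries in either tissue (adjusted p = 0.646, 0.915 and 0.543 in EEM). In brain, 8 of the 310 X-linked genes were at least 0.4 log2 higher in the female of both litters (2.58%, against 0.163% of autosomal genes). In EEM 8 of 242 were (3.31%, against 1.38%), and 4 genes were on both lists, where 0.271 would be expected of independent lists. The others lay on chromosome X at 3.47, 3.92, 14.4 and 79.0 Mb in brain and at 4.72, 32.8, 72.1 and 73.5 Mb in EEM, none of which passed the test. No X-linked gene was at least 0.4 log2 higher in the male of both litters in either tissue. The 0.4 limit was chosen after the values had been seen. With limits of 0.2, 0.3, 0.5, 0.6 and 1 the counts were 21, 15, 3, 3 and 2 in brain and 30, 15, 5, 5 and 2 in EEM. These counts lay above at least 99.8% of 10000 expression-matched sets of autosomal genes in brain and above at least 95.1% in EEM. The numbers higher in the male of both litters were 6 at 0.2, 1 at 0.3 and 0 at the higher limits in brain, and 11, 5 and 0 in EEM, none above more than 56.3% of the matched sets.

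**Figure D2:**
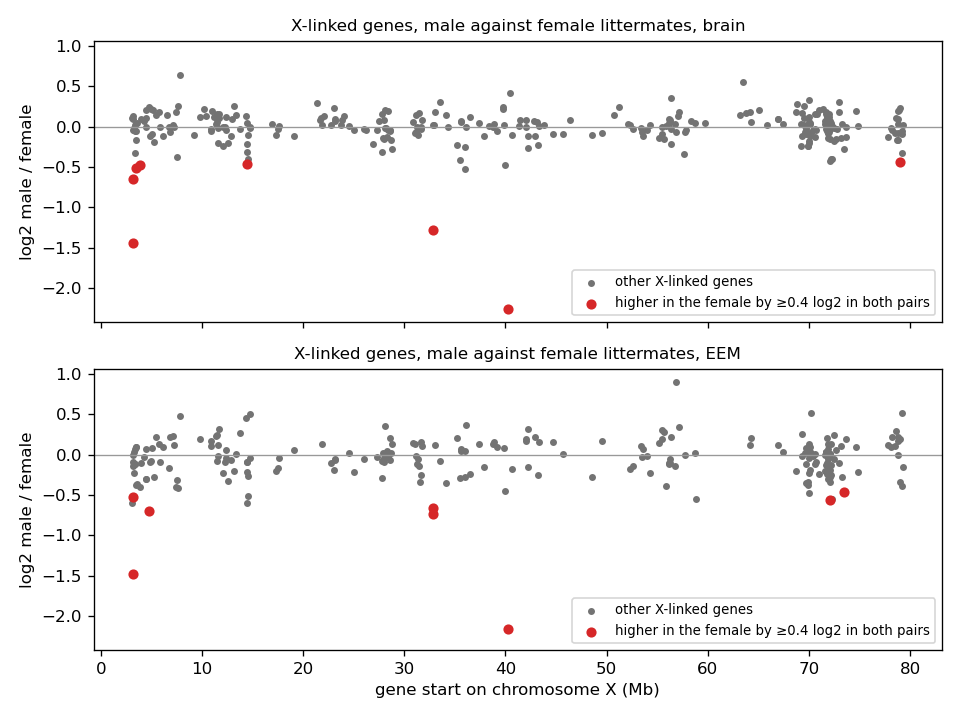
Log2 ratio of male to female expression (vertical axis, limma estimate from the 2 parental litters) of each X-linked gene with a mean of at least 1 FPKM against its start on chromosome X in Mb, in brain (310 genes, upper panel) and EEM (242 genes, lower panel). Red points are the 8 genes per tissue that were at least 0.4 log2 higher in the female of both litters, and grey points are all others; the gene at 40.3 Mb is lowest in both panels, at -2.26 and -2.16.

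As a set, X-linked genes differed little from autosomal genes by sex. Their median difference, male minus female, lay 0.0153 above the autosomal median in brain on the log2 scale (95% bootstrap interval over genes 0.000108 to 0.0335; camera p = 0.172, and p = 0.396 with an estimated correlation). In EEM it lay at -0.0322 relative to it (95% bootstrap interval over genes -0.0695 to -0.00268; camera p = 0.0588, and p = 0.478 with an estimated correlation). Both intervals exclude 0, in opposite directions, and the X-linked medians lay at percentiles 98.6 (brain) and 0.48 (EEM) of matched autosomal sets, while camera over all 8 libraries passed the threshold in neither tissue. In brain the median and the mean of the set differed in sign, and camera pointed to lower values in males. The sign of the difference also turned between the litters. It was -0.00948 in LL1xLL1 and 0.0346 in LL2xLL2 in brain, and -0.0996 and 0.0186 in EEM. Leaving out either embryo of a parental litter left the pair of the other litter, 1 male against 1 female, and gave the sign of that pair. In EEM the difference over both litters kept its sign without LL2xLL1 embryo 1 or embryo 4, at -0.03. The unadjusted camera values were 0.0450 and 0.0392. Of all brain genes tested, 0 of 13081 passed the limma test by sex, with 30 at an unadjusted p under 0.05, and 319 with a term for the F1 libraries numbered 4, when 2 passed. Fitted to the 4 parental libraries alone, with little left to estimate the spread, limma called 40 brain genes (32 higher and 8 lower in males) and 5 EEM genes. The EEM call of the gene at X 40254006 to 40263016 was lost without LL1xLL1 embryo 5, a fit that rests on the LL2xLL2 pair alone. Its log2 difference in EEM was -1.97 in the LL1xLL1 pair and -2.34 in the LL2xLL2 pair.

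The reciprocal F1 crosses, which carry the same pair of lines with the parents exchanged, were compared to ask whether expression follows the parent of origin. In EEM, 111 of 11873 genes differed (limma, adjusted p under 0.05), 38 higher and 73 lower in LL2xLL1 than in LL1xLL2, and 1 of these was X-linked. The highest differences were in 7 genes on 6 chromosomes that were 10.5- to 17.8-fold higher in both LL2xLL1 membranes. ENSMODG00000024992 on chromosome 7 (113038086 to 113039211) was at 793 ± 53.3 FPKM in LL2xLL1 and 43.5 ± 2.18 FPKM in LL1xLL2 (SD, n = 2 each; log2 4.16, SE 0.12, adjusted p = 1.05e-05 in limma), and at 26.6 to 34.0 FPKM in the 4 parental membranes. ENSMODG00000018689 on chromosome 2 (313838027 to 313839154) was at 3473 ± 318 FPKM in LL2xLL1 and 208 ± 18.4 FPKM in LL1xLL2 (SD, n = 2 each; log2 4.06, SE 0.13). These 7 genes have spans of 1083 to 1157 bp. Whether they share reads was not tested, and their separate values are uncertain. In brain, ENSMODG00000024992 was at 14.2 FPKM in LL2xLL1 and 15.1 FPKM in LL1xLL2.

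Among the genes that were lower in LL2xLL1 membranes, ENSMODG00000015449 on chromosome 1 (726794256 to 726802969) was at 5.01 ± 1.25 FPKM against 28.4 ± 1.68 FPKM (SD, n = 2 each; 4.94-fold lower, log2 -2.31, SE 0.19, adjusted p = 0.00453 in limma). ENSMODG00000025564 on chromosome 4 (240813609 to 240820353) was at 63.6 ± 42.6 FPKM against 472 ± 22.1 FPKM (SD, n = 2 each; 8.27-fold lower, adjusted p = 0.0467 in limma), a call that was lost at a pseudocount of 0.1 (adjusted p = 0.0610, in a range from 0.0134 to 0.110 over all alternative fits of limma). The gene on chromosome 8 at 189047014 to 189067519 was 5.36-fold lower, a call lost with the 4 F1 libraries alone (adjusted p = 0.0504 in limma) and without LL1xLL2 embryo 3 (adjusted p = 0.0624), in a range from 0.00731. The gene on chromosome 6 at 128238574 to 128578955 was 4.63-fold lower. In brain 0 of 13081 genes passed, with 47 at an unadjusted p under 0.05 in limma. That number moved with the split of the F1 brain libraries described below: it was 929 with a term for the libraries numbered 4, 161 without LL1xLL2 embryo 3, 198 without LL2xLL1 embryo 1 and 14 without any single parental library, with 0 genes past the adjusted threshold in each. Simulated differences of 2 log2 units were recovered for 29% of changed genes in this comparison and those of 1 log2 unit for 0%. The simulated data held neither that split nor litter effects, so recovery in the deposited data may differ. The brain gene nearest to the threshold with LL2xLL1 above LL1xLL2, on chromosome 7 at 154641485 to 154641864, was at 45.5 ± 0.174 and 29.7 ± 0.750 FPKM (SD, n = 2 each), and the gene on chromosome 5 at 237929014 to 237929099 was at 71.1 ± 26.9 and 205 ± 24.3 FPKM (SD, n = 2 each). The difference between the tissues in these effects was not tested. The EEM count was 44 with the 4 F1 libraries alone. It was 53 without either LL1xLL1 embryo, 54 and 51 without LL2xLL2 embryos 1 and 3, 45 without LL1xLL2 embryo 3, and 30 and 64 without LL2xLL1 embryos 1 and 4.

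The LL1xLL1 and LL2xLL2 litters were compared for differences between the lines. In EEM 70 genes differed (limma, adjusted p under 0.05), 43 higher and 27 lower in LL2, and none was X-linked. ENSMODG00000013862 on chromosome 1 (711241108 to 711253077) was at 39.3 ± 6.41 FPKM in LL2 and 3.5 ± 0.332 FPKM in LL1 (SD, n = 2 each; 8.90-fold, adjusted p = 0.0303 in limma). ENSMODG00000003239 on chromosome 6 (32268178 to 32275551) was at 103 ± 8.07 FPKM in LL2 and 15.3 ± 7.57 FPKM in LL1 (SD, n = 2 each; 6.77-fold, adjusted p = 0.0260 in limma). Lower in LL2 were ENSMODG00000000906 on chromosome 1 (52095132 to 52098582), at 1.51 ± 0.311 against 14.1 ± 0.776 FPKM (6.03-fold), and ENSMODG00000018257 on chromosome 4 (415222152 to 415622470), at 3.15 ± 1.03 against 14.9 ± 7.75 FPKM (3.66-fold; SD, n = 2 each). The gene on chromosome 1 at 200908629 to 200925855 was 5.09-fold higher in LL2 than in LL1 and, in the reciprocal comparison, 4.55-fold lower in LL2xLL1 than in LL1xLL2. The reciprocal call was lost without LL1xLL2 embryo 3 (adjusted p = 0.0794) or LL2xLL1 embryo 4 (adjusted p = 0.0671). Leaving out a parental embryo left 1 embryo of each line in the line comparison. Without either male (LL1xLL1 embryo 5 or LL2xLL2 embryo 3) it compared the females alone, and without either female it compared the males alone. Of these 5 EEM genes, ENSMODG00000003239 lost its line call in the females alone, and the other 4 lost theirs in both. In brain 0 genes passed, with 90 at an unadjusted p under 0.05 in limma, and 1453 with a term for the F1 libraries numbered 4, when 5 passed. The smallest p was that of the gene on chromosome 7 at 154641485 to 154641864, at 48.7 ± 2.91 FPKM in LL2 and 21.9 ± 0.551 FPKM in LL1 (SD, n = 2 each; 2.17-fold). Fitted to the 4 parental libraries alone, limma called 259 brain genes (190 higher and 69 lower in LL2) and 219 EEM genes. This fit too has little left to estimate the spread. In it the chromosome 7 gene had an adjusted p of 0.00110, the lowest in a range up to 1 over all alternative fits. The 23 mitochondrial genes had a median log2 difference of -0.16 in brain (camera adjusted p = 0.000464, and adjusted p = 0.968 with an estimated correlation). The EEM count was 17 without LL1xLL1 embryo 1 or LL2xLL2 embryo 1, and 2 without LL1xLL1 embryo 5 or LL2xLL2 embryo 3.

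F1 and parental fetuses were compared for differences between crosses of the lines and the lines themselves, and this comparison gave the most called genes in both tissues. Because all F1 fetuses were female, the sex term took up the parental males. Log2 changes, folds and limma p-values of this comparison thus set F1 against the parental females alone. The means and SDs printed beside them are over all parental fetuses. In EEM 5549 of 11873 genes differed (limma, adjusted p under 0.05), 2569 higher and 2980 lower in F1, and 2047 of them by more than 2-fold. In brain 1629 of 13081 genes differed, 458 higher and 1171 lower, 599 of them by more than 2-fold. Rescaling the libraries by their median ratios changed the brain split to 659 higher and 822 lower, and it shifted the median log2 difference of all brain genes by 0.10, from -0.07 to 0.03. Of the X-linked genes, 10.3% were called in brain (17 higher, 15 lower) and 45.0% in EEM (44 higher, 65 lower), against 12.5% and 46.9% of autosomal genes. Of 11144 genes tested in both tissues, 201 were higher in F1 in both (73.4 expected of independent lists), 693 were lower in both (287 expected) and 27 moved in opposite directions (318 expected). The changes in the 2 tissues correlated across genes (r = 0.508), which are not independent replicates, and both tissues came from the same fetuses.

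In brain, ENSMODG00000017307 on chromosome 1 (469229304 to 469232950) was at 145 ± 53.4 FPKM in F1 and 3.32 ± 0.959 FPKM in parental fetuses (SD, n = 4 each; 36.3-fold higher, adjusted p = 0.00434 in limma). ENSMODG00000010932 on chromosome 3 (200672868 to 200679107) was at 336 ± 165 against 10.6 ± 2.66 FPKM (SD, n = 4 each; 26.1-fold). The largest fall by log2 change was that of ENSMODG00000016637 on chromosome 6 (149446061 to 149446330), from 84690 ± 15004 FPKM in parental to 345 ± 182 FPKM in F1 brain (SD, n = 4 each; 268-fold lower, adjusted p = 0.00326 in limma). It was also lower in F1 membranes, at 2436 ± 1524 against 98051 ± 54572 FPKM (SD, n = 4 each; 43.0-fold, adjusted p = 0.000244 in limma). It spans 270 bp. ENSMODG00000016631, in the same stretch of chromosome 6 (149396740 to 149399115), was 110-fold lower in F1 brain, and the gene at 149374306 to 149398530, which overlaps it, was 12.3-fold lower. The values of these overlapping genes are uncertain because they may share reads. The brain calls named here were lost without LL1xLL1 embryo 1, a fit that compares F1 with the LL2xLL2 female alone. In EEM, ENSMODG00000013512 on chromosome 2 (196513533 to 196518891) was at 74.0 ± 31.5 against 0.258 ± 0.156 FPKM (SD, n = 4 each; 54.3-fold higher, adjusted p = 4.67e-05 in limma) and ENSMODG00000017397 on chromosome 2 (187864577 to 187865727) was 52.6-fold higher. ENSMODG00000003239, which differed between the lines, was at 0.313 ± 0.0974 FPKM in F1 and 59.2 ± 51.1 FPKM in parental membranes (SD, n = 4 each; 35.2-fold lower).

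Mitochondrial genes made up a smaller share of summed FPKM in F1 fetuses. It was 13.5% ± 1.84 against 20.9% ± 1.64 in brain and 21.3% ± 1.92 against 28.0% ± 4.09 in EEM (SD, n = 4 each). The median log2 change of mitochondrial genes under 100 bp (12 in brain, 11 in EEM) was -1.49 in brain and -1.33 in EEM. That of longer ones was -0.646 and -0.940, so very short genes may weigh on these shares. The median level of mitochondrial genes was 1528 against 4211 FPKM in brain and 2860 against 6358 FPKM in EEM. The exact permutation p was 0.0286 in each, the smallest possible, and 0.0762 after adjustment. These splits also exchange littermates, so the p-values do not measure the spread between litters. Of the 23 mitochondrial genes in brain 7 were called lower and 1 higher, and of the 25 in EEM 16 were called lower and 3 higher. The mitochondrial gene at 3776 to 3846, of 71 bp, was 14.3-fold lower in F1 brain and 28.4-fold lower in F1 membranes. As a set, mitochondrial genes had a median log2 difference of -0.70 in brain (camera adjusted p = 0.0167, and adjusted p = 0.996 with an estimated correlation) and -1.02 in EEM (adjusted p = 0.0448, and adjusted p = 0.784 with an estimated correlation). X-linked genes lay 0.16 above autosomal genes in F1 brain (camera adjusted p = 0.0242, and adjusted p = 0.733 with an estimated correlation) and at -0.03 relative to them in EEM (adjusted p = 0.864).

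F1 and parental fetuses differed in litter and mother, the labels give no library batch, and genotype and batch cannot be told apart here. The F1 brain libraries also split among themselves: LL1xLL2 embryo 4 and LL2xLL1 embryo 4 lay apart from LL1xLL2 embryo 3 and LL2xLL1 embryo 1 on the first principal component (53.0% of the variance). The rank correlation was 0.987 between the embryo 4 libraries of both litters and 0.995 between the other F1 libraries, against 0.885 and 0.875 within the LL1xLL2 and LL2xLL1 litters. Of 13081 genes, 892 were at least 1 log2 unit higher and 1170 at least 1 log2 unit lower in the embryo 4 library of both litters. The brain F1 count was 7060 without those 2 libraries and 6824 without the other 2, alternatives that were added after the data had been seen. Leaving out single libraries also changed the brain count: it was 553 without LL1xLL1 embryo 5, 566 without LL2xLL2 embryo 3, 764 without LL2xLL1 embryo 1 and 874 without LL1xLL2 embryo 3. In both tissues the lowest counts came without LL1xLL1 embryo 1 or LL2xLL2 embryo 1, the parental females. Those fits compare F1 with the other parental female alone, because the sex term takes up the parental males.

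**Figure D3:**
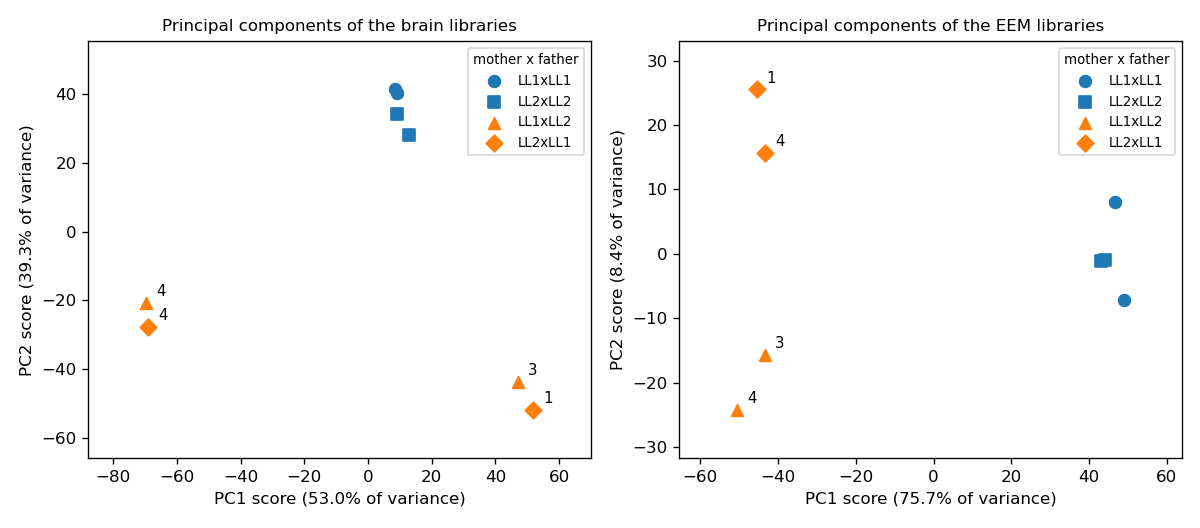
Scores of the 8 brain libraries (left) and the 8 EEM libraries (right) on the first and second principal components of log2(FPKM + 1), without a unit, with blue for parental and orange for F1 fetuses, a shape for each cross, and the embryo number beside each F1 library. In brain the 2 F1 libraries numbered 4 part from the other 2 along the first component (53.0% of the variance), and in EEM the first component (75.7%) parts F1 from parental libraries.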

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

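Several tests were chosen after the results they measure had been seen. They are those of membrane tissue by the spread of implied shares, of chance between pairs of littermates and of overlapping genes. The same holds for calls among longer genes, splits with a term for the F1 brain libraries numbered 4 and very short mitochondrial genes. No limit was set beforehand for the correlations of the F1 brain split with the tissues and with the EEM litter difference, or for those between its sides. The other tests were set before.

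In 56 groups of 4 libraries, 5 values stood far from the other 3, where chance alone gives about 1 in 20. The mitochondrial gene at 3776 to 3846 was at 668 FPKM in the F1 brain library LL1xLL2 embryo 3, against 286 to 337 in the other F1 brains. The mitochondrial gene at 14113 to 14182 was at 7300 FPKM in the parental brain library LL2xLL2 embryo 3, against 13002 to 14008. In EEM, the gene on an unplaced sequence at 47473676 to 47483718 was at 0.317 FPKM in LL1xLL1 embryo 1, against 0.725 to 0.739 in the other parental membranes. The gene on chromosome 2 at 500991326 to 500993068 was at 50.7 FPKM in LL2xLL2 embryo 3, against 10.3 to 16.7. The gene on chromosome 3 at 91645181 to 91692763 was at 1.61 FPKM in the F1 library LL1xLL2 embryo 4, against 0.238 to 0.405. Of 22 genes compared between tissues, 0 moved in opposite directions in every library.

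The 2 F1 brain libraries numbered 4 stood apart from the other 2, across litters. If the other 2 held membrane tissue, each of 9 genes that were abundant in F1 membranes and nearly absent from the libraries numbered 4 would rise by a like share of its membrane level; 6 of the 9 implied shares lay more than 10-fold under the largest, 13.7%. These 6 genes argue against membrane tissue of the composition measured here. Another value goes the other way. Over 12220 genes, the difference of the libraries numbered 4 from the other 2 correlated with that of parental brain from parental EEM (r = 0.251). No value of r without membrane tissue is known here. The other 2 also lay nearer to parental brain than the libraries numbered 4, with rank correlations of 0.918 to 0.947 against 0.906 to 0.919. The implied shares and r set against each other values of tables that appear to be normalized separately, which limits both. With 3 genes at shares of 6.27% to 13.7%, membranes of another composition stay open. The measure set beforehand, the share of these genes within 3-fold of the median, came to 55.6% and is void because the median share was 0. Exchanged litter labels cannot be told apart from a correct labelling, because over genes that differed between the F1 crosses in EEM the brain difference between litters correlated with that in EEM at 0.310 for embryos 1 and 3 and 0.204 for the embryos numbered 4, between the limits set beforehand. The EEM difference followed the split less, at 0.105, and the litter differences on both sides of the split correlated at 0.336 over these 89 genes and at 0.0484 over all genes tested in brain. A difference in dissected brain region or stage is a biological explanation that was not tested, as is a library batch, which the labels do not give.

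F1 and parental libraries differed in 1629 genes in brain and 5549 in EEM. In EEM 1 of 35 splits of the 8 libraries into 4 and 4 gave as many genes, the real one with 5549 and the highest other with 9. This share does not exclude chance, because littermates are not independent. The sex term, kept in each split, also makes splits with both males on 1 side unlike the others. In brain 3 of 35 did, the real one with 1629 and the others with 3820 and 2365; both of these set the F1 libraries numbered 4 against the other F1 libraries and point to that structure. With a term for those libraries, 1 of 31 distinct splits gave as many, the real one with 6777 and the highest other with 1, though that term was chosen on these data. In each tissue 3 splits keep litters whole, too few for a share under 0.05, the real one with the counts above and the highest other with 0. Genes with a span under 300 bp made up 3.07% of the calls in brain and 1.57% in EEM, a test that is void because they could have made up at most 13.6% and 3.39%. Longer genes were called at 12.3% in brain and 46.7% in EEM, and short genes at 22.5% and 46.3%. Many calls among longer genes were bound to follow as well, because so few short genes were tested. They show that short genes were not most of the calls. They cannot decide whether short genes shifted the values of the others. The median absolute change of short and longer genes was 0.56 and 0.35 log2 in brain, and 0.57 and 0.44 in EEM; these differences were not tested. A difference between library batches cannot be told apart from genotype, litter or stage, because either would move genes alike in both tissues (r = 0.508) and the F1 and parental groups share no litter. Of the mitochondrial genes under 100 bp, 9 of 12 were lower in F1 in brain and 7 of 11 in EEM, and of the longer ones 8 of 11 and 11 of 14. The median log2 change of the short genes minus that of the longer ones was -0.846 in brain and -0.389 in EEM, not tested against the spread among genes. As the EEM value lies between the limits set for it, a difference in fragment length may or may not contribute.

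Some X-linked genes were higher in females of both litters. The share at 0.4 log2 or more lay above 100% of matched autosomal sets in brain and 97.5% in EEM. It was thus higher than among autosomal genes of the same embryos. The sets draw genes as if they were independent, and both lists hold the overlapping genes at X 3.17 Mb. The limit was also chosen on these data, so chance between the pairs of littermates is not excluded. Of the 12 genes on either list 25% overlap another listed X-linked gene, which leaves reads shared through such overlap open for them. The other genes overlap no listed X-linked gene, which argues against that source for them. Whether they share reads with unlisted genes or with genes elsewhere was not tested. Expression from both X chromosomes in females is a hypothesis that these data do not separate from other sex differences, since allele ratios are not used here.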

How the results depend on the processing

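The fits with a term for the F1 brain libraries numbered 4, without pairs of F1 brain libraries or without genes under 300 bp, and the limits other than 0.4 log2, were chosen after the data had been seen. Depth is unknown, so what it limits cannot be stated. The causes of the changes below were not tested, except that fits of fewer libraries hold fewer samples. The planned tests of brain against EEM, of gene lists and of X-linked genes between tissues, the difference between tissues of each effect, the paired test of the X level and the X chromosome without genes with a Y copy were not run, because the tables were normalized separately and hold no symbols. No paired analysis was possible by replicate number because a number pairs the tissues of a fetus, whose tables were normalized separately, and any 2 crosses within a table share fewer than 2 numbers. F1 and parental fetuses with the same number come from different litters; male and female littermates were compared within their litters.

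For the male against female comparison, the brain count of 0 became 40 with the 4 parental libraries and 2 with the term for the libraries numbered 4, and the EEM count of 1 became 5 with the 4 parental libraries. For parental lines, the brain count of 0 became 259 and 5 in those fits, and the EEM count of 70 became 219 with the 4 parental libraries and 45 without a filter. For reciprocal F1 crosses in EEM, 111 became 66 and 59 at pseudocounts of 0.1 and 0.01 and 44 with the 4 F1 libraries. In brain the count was 0 in every fit. For F1 against parental in brain, 1629 became 545 with females only, 2531 with litter as a random block, where the estimated litter correlation was -0.686, a negative value that goes with the split of the F1 litters and makes the higher count no gain in evidence, 6777 with the term for the libraries numbered 4, 7060 without those 2 and 6824 without the other 2; all 1629 genes were among the 6777. Median ratio scaling gave 659 higher and 822 lower there, and 2783 higher and 2751 lower in EEM. The F1 count in EEM stayed within 1.5 times of 5549 under each setting that kept all libraries or females only.

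For X-linked genes higher in females of both litters, the count of 8 in brain became 21, 15, 3, 3 and 2 at limits of 0.2, 0.3, 0.5, 0.6 and 1 log2. The count of 8 in EEM became 30, 15, 5, 5 and 2, and 13 and 16 at pseudocounts of 0.1 and 0.01 and 5 at a minimum of 5 FPKM. The X-linked minus autosomal sex difference in brain was 0.00345 at a minimum of 5 FPKM (unadjusted camera value 0.0143, against 0.172). The X-to-autosome ratio in brain was 1.09 at a minimum of 5 FPKM, 1.19 over genes of at least 1 FPKM in both tissues and 1.15 as a trimmed mean; in EEM it was 0.803 over all genes and 1.10 at a minimum of 5 FPKM. Its F1 minus parental difference was 0.176 in brain with females only, close to 0.181 over all libraries (exact p = 0.0667, the smallest that 15 splits allow, so this test could not pass 0.05). In EEM, where it was -0.00469, it became -0.0633 over all genes (exact p = 0.0286) and turned to 0.0418 at a minimum of 5 FPKM and 0.000498 over genes in both tissues.

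Leaving out each library in turn, assuming that a lone library varies like the other groups, gave 0 to 1510 genes for F1 against parental in brain and 3563 to 5405 in EEM, 0 to 11 for sex, 2 to 88 for lines and 30 to 98 for reciprocal crosses in EEM, and 0 in brain for these last 3 comparisons. The lowest brain F1 counts came without LL1xLL1 embryo 1 or LL2xLL2 embryo 1, the parental females. As the sex term takes up the parental males, these fits compare F1 with the other parental female alone. The X-to-autosome ratio ranged from 0.934 to 0.970 in brain and 1.02 to 1.05 in EEM. Its F1 minus parental difference ranged from 0.166 to 0.192 in brain and from -0.0357 to 0.0424 in EEM, positive without LL1xLL1 embryo 1 (0.00387) or LL1xLL2 embryo 4. The X-linked sex difference ranged from -0.00937 to 0.0345 in brain, negative without LL2xLL2 embryo 1 (-0.00902) or 3, and from -0.0996 to 0.0187 in EEM, positive without either LL1xLL1 embryo. Each end of these ranges rests on the male and female of a single litter, so the litters differed in sign.

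For the 49 named results past the threshold (a gene counts in each comparison that names it), 16 of 417 values under other settings and 92 of 392 with a library left out were no longer past it, 0 changed direction, and 20 stayed past it in all.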

Other observations

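The tests of neighbouring genes were chosen after the sex differences had been seen; the test of the mother's X chromosome was set before.

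The sex difference of X-linked genes was shared between tissues to a limited extent. Across the 236 X-linked genes tested in both tissues the male-to-female differences correlated with r = 0.598 and rho = 0.165, and r was 0.257 without the 4 genes on both lists, so much of it rests on those genes. Autosomal genes gave r = 0.0158. Genes are not independent replicates, and both tissues came from the same fetuses. The genes at X 32791265 to 32850277 and X 32853494 to 32887286 lie next to each other and were 1.58-fold and 1.67-fold higher in females in EEM, and the genes at 3.17, 3.47 and 3.92 Mb in brain lie within the first 4 Mb of the chromosome. A candidate explanation, that genes higher in females lie in shared domains, was tested on neighbouring X-linked genes that do not overlap. The correlation of their sex differences was 0.0556 in brain (permutation p = 0.138) and 0.117 in EEM (permutation p = 0.0414), and autosomes gave -0.00130 to 0.147, so the X chromosome did not stand apart and the explanation stays open.

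If X-linked genes in F1 females are expressed from the mother's X chromosome, their difference between reciprocal crosses may follow the difference between the lines. This hypothesis was tested as the correlation, across X-linked genes, of the LL2xLL1 minus LL1xLL2 difference with the LL2 minus LL1 difference. It was 0.190 in brain, at percentile 51.7 of matched autosomal sets, and -0.173 in EEM, at percentile 13.5. In EEM the rank correlation had the other sign, rho = 0.0597, and 8 of the 12 X-linked genes that differed between the lines by more than 0.5 log2 shared the sign of the line difference (66.7%, against 47.1% of autosomal genes). The genes with the largest line differences did not share it. They lay at X 69731212 to 69744054 (line 2.71, reciprocal -1.82) and X 72059664 to 72064041 (line 1.43, reciprocal -1.67). In brain rho was 0.148 and 2 of 6 such genes shared the sign (33.3%, against 68.1%). Neither lay above the 95th percentile that the hypothesis asked for. The test cannot decide, because so few X-linked genes differed between the lines and both differences come from single litters.

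The reciprocal differences of X-linked genes correlated between brain and EEM with r = 0.379 across 236 genes, against 0.171 for autosomal genes; whether these values differ was not tested.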
